A study of Mus musculus with 38 samples.

How the data were processed

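RNA levels were measured in mouse livers with 2-colour long-oligonucleotide arrays, 38 in all, covering 20 mice in 4 groups of 5. Per the series' design text, every mouse received 1 intraperitoneal dose of N-nitrosodiethylamine (DEN), a hepatocarcinogen, at 10 micrograms per gram of body weight when 14 days old, and livers were examined 3 or 5 months after it. The labels give ages of 12 and 20 weeks for these mice, which is earlier than 3 and 5 months after a dose at 14 days. The groups are called 3 and 5 months here, and the time since the dose is not settled. The knockout mice lacked c-Met, the receptor of hepatocyte growth factor, in hepatocytes through a Cre recombinase driven by the albumin promoter, and the control mice carried the same Cre without the floxed alleles, per the labels. Each liver was hybridised against one common reference, RNA pooled from 5 wild-type male livers aged 12 weeks, per the labels and the series' design text. Total RNA came from snap-frozen tissue by caesium chloride gradient, per the labels' protocols. Both dye orientations were hybridised for 18 mice. Of the remaining mice, 5-month knockout animal 2 has an array with liver in Cy3 alone here and 5-month knockout animal 3 one with liver in Cy5 alone.

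The authors excluded invalid features and normalised each array in the mAdb suite to its median signal (50th percentile), per the series' design text. The deposited values are log2 ratios of both dyes, 1 per probe and array, for 36607 probes, and no probe lacks a value in any array. Base 2 was read from the steps between values. Background handling, averaging of spots and the direction of the ratio are not given in the sources used here. Array medians are not 0. With the liver in Cy5 they ran from -0.65 to -0.34 on the 10 arrays of 3 months and from -0.10 to 0.09 on the 9 arrays of 5 months. With the liver in Cy3, as deposited and before turning, they ran from -0.38 to -0.17 and from -0.27 to -0.04. Turning changes the sign of the latter. The signal behind each ratio is not in the values, so no dim-probe filter could be set, and the number of arrays limits the precision.

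Direction was settled in part. The 200 probes with the smallest p in the liver-in-Cy5 arrays alone were compared with the liver-in-Cy3 arrays after those were turned. The genotype difference had the same direction in 156 at 3 months and 148 at 5 months. Ranking by the Cy3 arrays gave 142 and 179 of 200. Over all probes the share with the same direction was 57.2% at 3 months and 55.1% at 5 months. The deposited values were therefore taken to follow the dyes and not liver over reference. The direct check is mixed. Before turning, both arrays of a mouse correlated at r = 0.34 to 0.51 across probes in the 10 mice of 3 months, where values that follow the dyes would mirror, and at -0.70 to 0.18 in 8 mice of 5 months. With the mean of the same orientation and age removed, r was -0.29 to 0.01 at 3 months (7 of 10 negative) and -0.27 to 0.09 at 5 months (7 of 8 negative), and over the most variable probes -0.07 to 0.07 (3 of 10 negative) and -0.07 to 0.21 (2 of 8 negative). Over the 300 probes farthest from the reference, before turning, r was -0.08 to 0.14 at 3 months and -0.82 to -0.23 at 5 months. These probes were picked on turned values, which favours mirroring. At 5 months the correlations are mixed. At 3 months they show little mirroring, so there the reading rests on the genotype differences alone. Which dye is the numerator is stated nowhere in the labels. Cy5 over Cy3 was taken as likely, after the values had been seen, because it is the common convention and because H19 and Afp, fetal liver genes that adult liver barely expresses, then lie above the normal reference in some DEN-treated livers. The opposite reading would exchange higher and lower in every statement. The scale is log2, the centring stays as deposited, and the numerator stays unproven. The liver-in-Cy5 array of 5-month control animal 4 stood apart from the 10 liver-in-Cy5 arrays of 3 months (r = -0.61 to -0.48 across probes). Its own sign is not in doubt, since after turning it correlated with the liver-in-Cy3 array of the same mouse at 0.70. Over the 300 probes farthest from the reference in the other 4 controls, it correlated at 0.67 to 0.80 with their arrays. Over all probes it did so at 0.14 to 0.27 with their liver-in-Cy5 and 0.59 to 0.72 with their liver-in-Cy3 arrays. Counts are also given without the array of control animal 4. That check, and the look at 5-month knockouts by array series, were chosen after the values were seen.

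Each array was turned to liver over reference, a probe-specific dye effect (estimated from the 18 mice with both orientations) was subtracted, and the arrays of a mouse were averaged to 1 value. The dye effect cancels for mice with both orientations and so acts only through the other 2. Probes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, over all 20 mice with 1 shared spread per probe, and p-values were adjusted by Benjamini-Hochberg over 36607 probes at a threshold of 0.05. Every adjusted p for a probe in the text is from this limma model and is 2-sided. The comparisons were knockout against control at each time, 5 against 3 months within each genotype, and the interaction of both. Sets of genes were tested with cameraPR on moderated statistics of 1 probe per gene with a preset correlation of 0.01 between genes, again with the correlation estimated from the residuals, and with fry, each adjusted over 40 lists within a comparison. The authors' own test, per the series' design text, was a univariate 2-sample test with a random variance model at an unadjusted threshold of 0.001, and it was rerun on the same values as the methods' t-test.

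Gene symbols came from the platform annotation. Of the 36607 probes, 26926 had 1 symbol, 203 had several and 9478 had none, and 26774 of the named ones matched a mouse RefSeq gene (assembly GRCm38.p6, used for names and neighbours only) by Entrez ID. A gene with several probes, as 5886 of 17501 genes had, was represented by the first in table order. Probes without a single informative symbol are counted but not named. Groups, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. That rule takes Met, the probes with the largest changes among those called in each direction (10 for genotype, 6 for time) or, where under 5 passed, the 5 with the smallest p, and members of each list. Members of lists that neither passed nor held a called gene are not named, nor, for time, those of lists that fail with the estimated correlation, a narrowing chosen after the values were seen, with the circadian clock genes as an exception chosen then too.

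The procedure was tested on simulated data with 36607 probes, the real spread and known changes, which was run after a first look at the real results. Of 1.5-fold changes it recovered 1.5% at 3 months, 6.0% at 5 months and 1.5% for the interaction. Between ages it recovered 4.5% in controls and 10.4% in knockouts. Where few probes change, as simulated, the procedure thus mostly misses changes of that size. For knockout against control it recovered 47.8% of 2-fold and 71.2% of 4-fold changes at 3 months and 41.8% and 75.8% at 5 months, for the interaction 19.4% and 66.7%, and for 5 against 3 months 41.8% and 83.3% in controls and 40.3% and 77.3% in knockouts, with 0 wrong directions and 0, 6, 1, 4 and 6 false calls in that order. Each simulated comparison changed 66 or 67 probes of each size, with the same dye effect at both ages. In the real data limma called 5369 probes between ages in controls, of which 1069 differed over 2-fold. The simulated recovery and false calls therefore do not carry over to the age comparisons. Arrays were also grouped by runs of consecutive array numbers in the labels, taken as array series, which the simulation left out. Series A holds all 5-month controls and 2 of the 5-month knockouts, series B the other 3 knockouts, and series C and D split the 3-month mice into 3 controls with 2 knockouts and 2 controls with 3 knockouts. Each series holds 1 time point, so time and array series cannot be told apart. Alternatives covered the dye correction, per-array fits, centring, quantile normalisation, variance moderation, the test, the array series, single orientations, averaging probes, single-array mice and leaving out each mouse. Figures were drawn with matplotlib 3.10.9. Labels give separate animals as replicates.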

Results

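Livers of mice with and without hepatocyte c-Met were profiled on 38 arrays after a single DEN dose, with 5 mice per genotype and time. The times are called 3 and 5 months, per the series' design text, though the labels' ages leave the time since the dose unsettled. The question was what loss of this growth factor receptor does to liver gene expression during chemical carcinogenesis. Values are log2 ratios of liver over a pooled normal liver reference, 1 per mouse, and errors of fold changes are standard errors from limma with n = 5 per group. Directions take the deposited ratio as Cy5 over Cy3, which is likely but not stated. The opposite reading would exchange higher and lower throughout.

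Met itself, the targeted gene on chromosome 6, was measured by a single probe. Its mean log2 ratio was -0.81 ± 0.18 (SD, n = 5) in 3-month controls and -0.39 ± 0.38 in 3-month knockouts, and -0.73 ± 0.30 and -0.78 ± 0.45 at 5 months. Met was not lower in knockouts at 3 months (log2 fold change 0.42 ± 0.21, above the control mean in 5 of 5 mice, adjusted p = 0.655) or detectably so at 5 months (-0.05 ± 0.21, adjusted p = 0.979, below the control mean in 2 of 5 mice). The labels do not say which part of the gene is deleted or where this probe lies, and livers also hold cells in which the gene is intact, so the probe may check nothing about the genotype labels. The 5-month sign turned without knockout animal 3 (0.14) or control animal 5 (0.04), within array series A (0.13) and with quantile normalisation (0.05).

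At 3 months, knockout livers differed from controls in few genes. Igfbp1, a secreted binding protein for insulin-like growth factors that insulin represses, was 2.57-fold higher (log2 1.36 ± 0.22, above the control mean in 5 of 5 knockouts, adjusted p = 0.0482). Its values were -1.61 ± 0.39 in controls and -0.24 ± 0.14 in knockouts (SD, n = 5). Acad9, a mitochondrial acyl-CoA dehydrogenase and complex I assembly factor, rose by 0.89 ± 0.15, and H2-Bl, a class I histocompatibility gene, by 1.05 ± 0.18, each in 5 of 5 knockouts with adjusted p = 0.0482. A further probe of Acad9 gave 0.22. Ctsc, the lysosomal protease cathepsin C, had the largest difference, 8.09-fold lower in knockouts (log2 -3.02 ± 0.51, 5 of 5 mice, adjusted p = 0.0482), with a further probe at -0.72 that did not pass.

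Other genes near the threshold at 3 months did not pass. Lgr4, a receptor for R-spondins that potentiates Wnt signalling, gave -1.04 ± 0.19 with adjusted p = 0.0690. Them7 gave -0.64. The apolipoprotein L gene Apol6 gave -1.31 and the odorant receptor gene Olfr771 -1.12, with adjusted p from 0.0830 to 0.0848. Fmn2, an actin-nucleating formin, gave 0.98 (adjusted p = 0.0691) and Lrtm1 0.92 (adjusted p = 0.0848). Through a later probe, and chosen after their values were seen, 2 further genes were called. Cyp3a13, a cytochrome P450 gene, gave 1.61 ± 0.22 (adjusted p = 0.0199) against 1.37 and 0.21 for its other probes. The class I gene H2-D1 gave -1.46 (adjusted p = 0.0482) against 0.09 for its other probe.

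Limma called 13 of 36607 probes at 3 months, 6 higher and 7 lower, for 6 named genes. The other 7 probes carry no single gene symbol. With array series as a covariate all 13 kept call and direction (Igfbp1 1.32, Ctsc -2.99), among 27 called. Within series C or D alone, with 5 mice each, limma called 0, and over both 2915 probes had an unadjusted p under 0.05. The calls sit close to the threshold. Fitting the 3-month mice alone gave 0, and leaving out 3-month control animal 2 or knockout animal 1 gave 0 as well. Dropping the liver-in-Cy5 array of 5-month control animal 4, which acts here through the shared spread, gave 1. The methods' t-test called 83 at its unadjusted threshold and 0 after adjustment.

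Among gene groups at 3 months, pericentral and Wnt-target liver genes, which mark hepatocytes around the central vein, were higher in knockouts as a set. Their 15 measured members had a median log2 fold change of 0.25 (adjusted p = 0.000274, adjusted p = 0.00115 with an estimated correlation, fry adjusted p = 0.0237). Limma called 0 of the 15 over all probes, and 2 rose when adjusted over the list alone. These were Rhbg, an ammonium transporter, at 0.61 ± 0.13 and Oat, ornithine aminotransferase, at 0.77 ± 0.20. In array series C alone the set gave 0.20 with adjusted p = 0.0623. Genes of glucose and glycogen metabolism also passed (14 measured, median 0.10, adjusted p = 0.00129, adjusted p = 0.191 with an estimated correlation). Igfbp1 rose in that list, and 2 members rose when adjusted over the list alone. Its median was 0.03 without 3-month control 5 and 0.16 without control 4.

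HGF and Met signalling genes had a median of 0.12 over 20 members (adjusted p = 0.0328, adjusted p = 0.238 with an estimated correlation). Limma called 0 of them over all probes or adjusted over the list alone. Its leading members were the serine protease gene St14 (0.55 ± 0.22) and Spint2, an inhibitor of the HGF activator (0.31 ± 0.13). Neither passed (adjusted p = 0.516 and 0.558), and their further probes lay between -0.12 and 0.05. Oxidative phosphorylation genes were lower as a set (24 measured, median -0.23, adjusted p = 0.00334, adjusted p = 0.688 with an estimated correlation). Limma called 0 members over all probes and 0 adjusted over the list alone, with Ndufb5 at -0.36 and Sdhd at -0.34. The set test called 4 of 40 lists, 1 with the estimated correlation and 1 by fry, and other splits of the same mice reached up to 9. The remaining 36 lists had adjusted p from 0.0524 to 0.903 and medians from -0.20 to 0.13. Their members called over all probes were Ctsc, in the periportal list, and Igfbp1, in the growth hormone and IGF axis. When adjusted over the list alone, 5 rose and 6 fell. Cell type marker lists were among these 36, with Kupffer cell and macrophage markers at a median of -0.11.

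**Figure D1:**
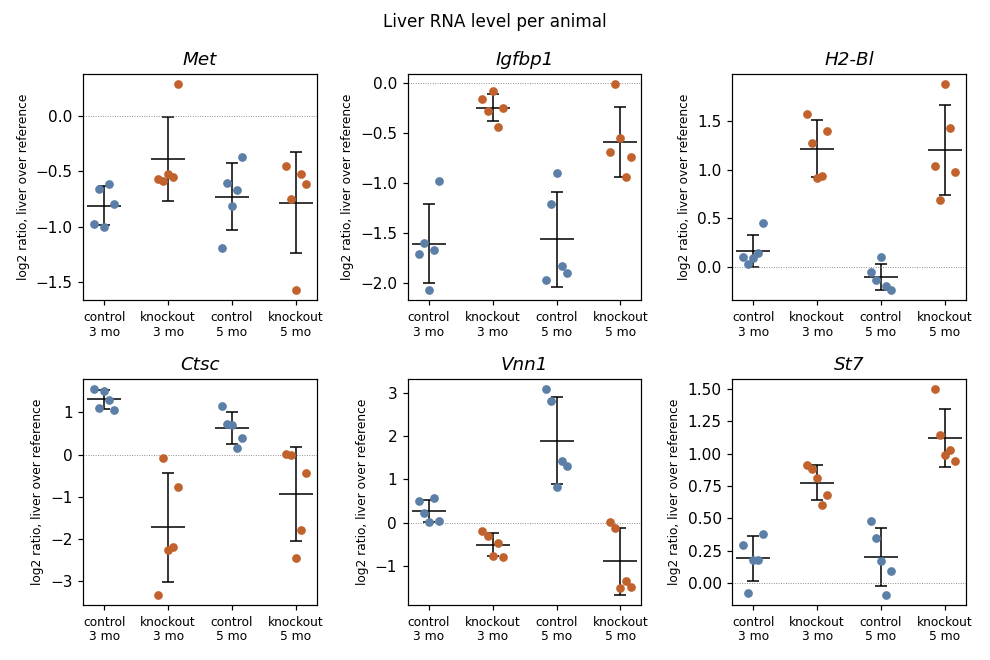
Log2 ratio of liver over reference for 6 genes, 1 point per mouse (n = 5 per group), with the bar at the mean and whiskers at 1 SD. Met does not fall in knockouts, Igfbp1, H2-Bl and St7 lie higher in knockouts at both times, Ctsc and Vnn1 lie lower, and the differences called were Igfbp1 and Ctsc at 3 months, Vnn1 and St7 at 5 months and H2-Bl at both.

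At 5 months the knockout livers showed more called genes, most of them higher. The lipid transporter gene Abca3 rose 2.78-fold (log2 1.47 ± 0.22, adjusted p = 0.0103). The interferon-inducible GTPase gene Gbp4 rose 2.64-fold (1.40 ± 0.19) and H2-Bl 2.46-fold (1.30 ± 0.18), both with adjusted p = 0.00790. Each lay above the control mean in 5 of 5 knockouts, and rises and falls here are against controls of the same age. Abca3 was at -1.50 to -0.48 in 5-month controls, -0.02 to 0.40 in 3-month controls and -0.67 to 0.69 in 5-month knockouts. Gbp4 was at -1.72 to -1.01, -0.48 to 0.70 and -0.22 to 0.41 in these groups. For these 2 genes it is the 5-month controls that lie apart. H2-Bl differs from them, at -0.23 to 0.11, 0.03 to 0.45 and 0.69 to 1.87. Id3, an inhibitor of basic helix-loop-helix transcription factors, rose by 1.23 ± 0.20 and Glo1, which detoxifies methylglyoxal, by 1.06 ± 0.15. Vnn1, a pantetheinase gene and PPAR-alpha target, was the largest named decrease, 6.88-fold (log2 -2.78 ± 0.39, 5 of 5 knockouts, adjusted p = 0.00790). Its means were 1.89 ± 1.00 in controls and -0.89 ± 0.77 in knockouts (SD, n = 5). With array series as a covariate Id3 gave 0.76 (adjusted p = 0.288) and Vnn1 -1.95 (adjusted p = 0.191), where Vnn1 in knockouts 1 and 2 of series A was at 0.02 and -0.12 and in those of series B at -1.50 to -1.35. The organic anion transporter gene Slc22a7 fell 2.01-fold (adjusted p = 0.0478).

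The other named increases were Zfp36l1, an mRNA decay factor (1.07 ± 0.20, with further probes at 1.08, 1.18 and -0.04), the acetyltransferase family gene Nat8f5 (1.07 ± 0.21) and Oat (1.03 ± 0.20). The RNA-binding gene Cpeb2 (1.01 ± 0.19) and Pebp1, the Raf kinase inhibitor protein (0.99 ± 0.16), also rose. Their adjusted p ran from 0.0158 to 0.0478, and 5 of 5 knockouts lay above the control mean for each. Ccdc14 fell by 0.71 on the log2 scale (SE 0.14, adjusted p = 0.0478), although a further probe gave 0.21. Colec10, a liver collectin, gave -0.65 ± 0.13, just short of the threshold, and Kank4 -0.68 ± 0.15 (adjusted p = 0.0944), so neither passed. Among neighbours of Met on chromosome 6, St7 rose by 0.92 ± 0.14 (adjusted p = 0.00972, further probes at 0.81 and 0.15). Capza2, an actin capping protein gene, rose by 0.77 ± 0.13 (adjusted p = 0.0187, a further probe at 0.70). These were the 2 of 17 measured neighbours that rose, over all probes and adjusted over the list alone, and the list as a set did not pass (median 0.02, adjusted p = 0.213).

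Limma called 53 probes for 35 genes at 5 months, 47 higher and 6 lower. All 53 had the same direction in the liver-in-Cy5 and in the liver-in-Cy3 arrays, which calling them on the mean of both favours. Over all probes the differences of both orientations correlated at r = -0.01, and 55.1% had the same sign. Array series B holds knockouts alone, so with series as a covariate only knockouts 1 and 2 are compared with controls. Limma then called 0, with 3440 at an unadjusted p under 0.05, and within series A alone it called 2. All 53 probes kept their direction under that covariate with an unadjusted p under 0.05, and their median size went from 0.92 to 0.87. They had been called with knockouts 1 and 2 and the same controls in the fit, which favours this. Over all probes the differences with and without the covariate correlated at r = 0.76. Fitting the 5-month mice alone gave 4, and dropping the liver-in-Cy5 array of control animal 4 gave 40. Leaving out control animal 4 gave 10, and leaving out control animal 3 gave 105. The methods' t-test called 186 at its unadjusted threshold and 4 after adjustment. H2-Bl was the 1 probe called at both times, and 40 of the 53 had the same direction at 3 months. Across all probes the genotype differences at the separate ages correlated at r = 0.12 (probes are not independent replicates).

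Several groups of hepatocyte metabolic genes were higher in the 5-month knockouts. Xenobiotic-metabolising cytochromes P450 had a median of 0.44 over 31 genes (adjusted p = 7.68e-08, adjusted p = 0.0568 with an estimated correlation, fry adjusted p = 0.0152). Limma called 0 members over all probes and 9 adjusted over the list alone, among them Cyp3a44 (0.78 ± 0.20) and Cyp2c29 (0.66 ± 0.18). Amino acid and urea metabolism genes had a median of 0.40 over 22 genes (adjusted p = 1.18e-07, adjusted p = 0.0737 with an estimated correlation, fry adjusted p = 0.0191). Oat was called over all probes and 11 members when adjusted over the list alone. Glutathione and antioxidant enzymes had a median of 0.24 over 39 genes (adjusted p = 5.08e-05, adjusted p = 0.181 with an estimated correlation). Limma called 0 members over all probes and 3 adjusted over the list alone, with Gstm2 at 0.74 and Gstm3 at 1.10. Male-biased liver genes (median 0.39 over 11, Cyp2d9 0.49, Susd4 0.60), bile acid genes (0.16 over 23, Akr1c6 0.63, Cyp27a1 0.54) and hepatocyte markers (0.17 over 15, Cps1 0.80, Tat 0.68) passed with adjusted p = 0.00355, 0.0373 and 0.00494. Their adjusted p with an estimated correlation was 0.190, 0.233 and 0.506. Without 5-month control 4 hepatocyte markers gave 0.06 and no longer passed (adjusted p = 0.336). No member was called over all probes, and 1, 2 and 0 members rose when adjusted over the list alone. Leaving out 1 mouse gave 0.52 to 1.00 for Cps1 and 0.39 to 0.88 for Tat, and the call of bile acid genes ended without any 1 of 5 mice.

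Genes of energy and protein synthesis were likewise higher as sets at 5 months. Between 3 and 5 months their medians changed more in controls than in knockouts, a contrast that also compares array series. Oxidative phosphorylation changed by -0.60 in controls and -0.15 in knockouts, and ribosomal proteins by -0.61 and -0.16. Heat shock genes changed by -0.70 and -0.20, and endoplasmic reticulum stress genes by -0.60 and -0.06. Oxidative phosphorylation genes had a median of 0.31 over 24 (adjusted p = 6.91e-07, adjusted p = 0.233 with an estimated correlation), with Ndufv1 and Ndufa9 at 0.42 each. Limma called 0 of them over all probes or adjusted over the list alone. Ribosomal protein genes had a median of 0.31 over 27 (adjusted p = 9.87e-07, adjusted p = 0.190 with an estimated correlation), with Rpl32 called (0.83 ± 0.16) and 8 adjusted over the list alone. Heat shock genes passed (median 0.40 over 12, adjusted p = 0.000149, adjusted p = 0.117 with an estimated correlation), 6 of them rising when adjusted over the list alone. The chaperone gene Hsp90aa1 had a fold of 2.00, with further probes at -0.32 and 0.98 on the log2 scale, and Chordc1 gave 0.45. Endoplasmic reticulum stress genes passed as well (median 0.31 over 19, adjusted p = 0.000132, adjusted p = 0.181 with an estimated correlation), with Hsp90b1 at 0.63, Syvn1 at 0.75 and 4 adjusted over the list alone. With array series as a covariate Hsp90b1 gave 0.41, Syvn1 0.40 and the list 0.19 (adjusted p = 0.0373), and Ndufv1 gave 0.64. Pericentral and Wnt-target genes again were higher (median 0.20 over 15, adjusted p = 0.0216, adjusted p = 0.117 with an estimated correlation), with Oat called and 3 adjusted over the list alone. Fatty acid oxidation and PPAR-alpha targets were the single list that fell (median -0.15 over 27, adjusted p = 0.000132, adjusted p = 0.257 with an estimated correlation). Its 1 called member, also the 1 adjusted over the list alone, was Vnn1. With array series as a covariate the list gave -0.08 and adjusted p = 0.465.

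Of the marker lists of cells other than hepatocytes, those of endothelial cells and of Kupffer cells and macrophages passed in cameraPR. The others did not, with medians from -0.17 (neutrophils) to 0.36 (MHC class II and dendritic cells). Endothelial cell markers were higher in knockouts (median 0.28 over 16, adjusted p = 0.000476). It was the single list at this age to hold with an estimated correlation (adjusted p = 0.00147, fry adjusted p = 0.000129). Limma called 0 members over all probes and 7 adjusted over the list alone. The Fc receptor gene Fcgr2b of liver sinusoids gave 0.55 ± 0.12 and the adhesion gene Pecam1 0.37 ± 0.11, each above the control mean in 5 of 5 knockouts, and neither passed alone (adjusted p = 0.0759 and 0.261). A further probe of Fcgr2b gave -0.25. With all mice in, Kupffer cell and macrophage markers had the largest median among lists that passed (0.46 over 15, adjusted p = 8.58e-05, adjusted p = 0.181 with an estimated correlation). Clec4f was at 0.56, the lysosomal protease gene Ctss at 0.79, and 4 members passed adjusted over the list alone. Without 5-month control 5 the median was 0.30. With array series as a covariate the list gave 0.21 (adjusted p = 0.0967) and Ctss 0.37. Interferon response and antigen presentation genes (0.16 over 28, Bst2 0.63, Oasl2 0.46, 4 adjusted over the list alone) passed with adjusted p = 0.0429, and gave adjusted p = 0.506 with an estimated correlation. With array series as a covariate their median turned to -0.04 (adjusted p = 0.660). Stellate cell and matrix markers, with a median of 0.06, did not pass in cameraPR (adjusted p = 0.0710) but did by fry (adjusted p = 0.0236). Dcn, the matrix proteoglycan decorin, was called (0.55 ± 0.11).

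At 5 months 15 of 40 lists passed, 14 higher and 1 lower, 1 of them with the estimated correlation, and 6 lists passed by fry. Other splits of the same mice reached up to 17. The 25 others had adjusted p from 0.0572 to 0.939, among them liver tumour markers (median 0.17, adjusted p = 0.243, 0 called over all probes, 3 adjusted over the list alone) and cell cycle genes (0.03, adjusted p = 0.615, 0 called and 2 adjusted over the list alone).

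**Figure D2:**
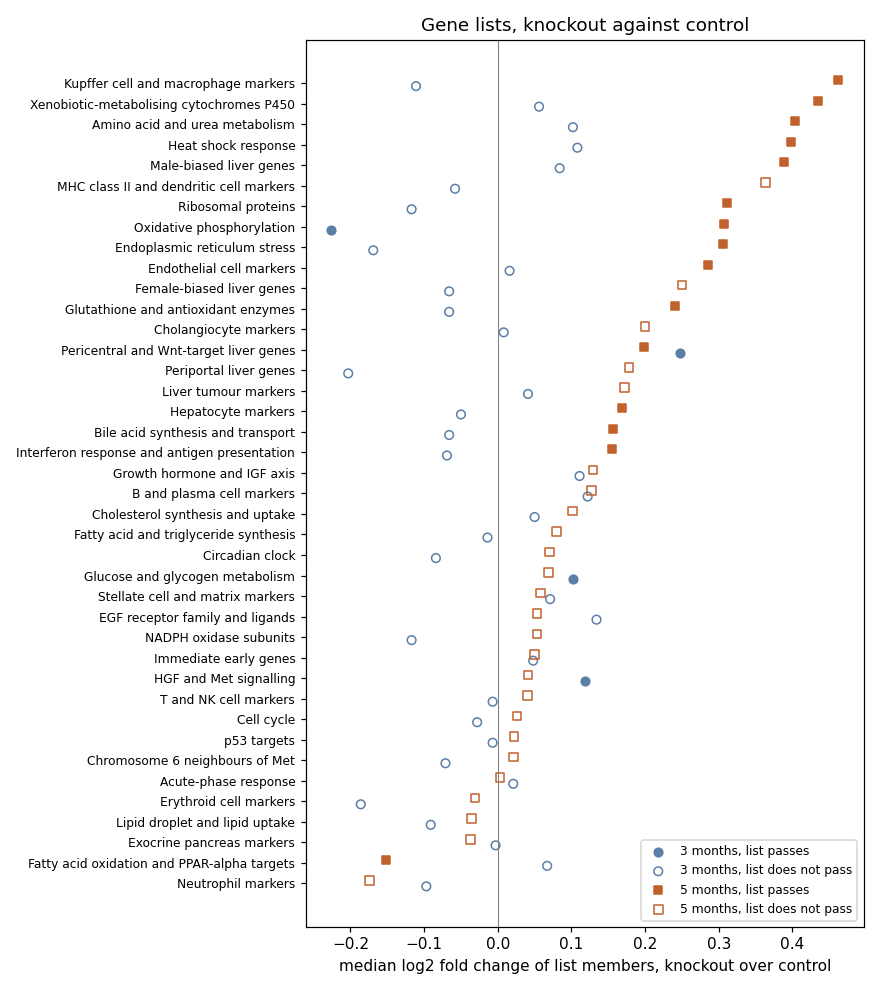
Median log2 fold change of the measured members of each of 40 gene lists, knockout over control, at 3 months (circles) and 5 months (squares), with filled symbols for lists that passed at the preset correlation. At 5 months 14 lists lie higher and 1 lower among those passing, against 3 and 1 at 3 months.

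Whether the genotype difference changed with age was tested as an interaction. The genes with the smallest p were Gbp4, whose difference was 1.54 ± 0.28 more positive at 5 months, and the clock repressor gene Nr1d1 (1.39 ± 0.26, with further probes at -0.22 and 1.07). Olfr771 (1.57), Csad, a taurine synthesis enzyme (1.39), and Rpl32 (1.11) followed. In the other direction were Ccdc14 (-0.92), Lipi (-0.86), Acad9 (-0.96), Zfp780b (-0.83) and Noc3l (-0.79). None passed (adjusted p from 0.366 to 0.431). Limma called 0 probes, with 2835 at an unadjusted p under 0.05 and 79 under 0.001. A fit of single arrays with the mouse as a random block called 149. Its estimated correlation between the 2 arrays of a mouse was -0.04, so it in effect counted arrays as replicates. In the fit of 1 value per mouse, no gene called at one age is thus shown to differ in its genotype effect between ages. As sets, 12 lists passed, led by oxidative phosphorylation (0.55, adjusted p = 2.83e-10) and ribosomal proteins (0.51, adjusted p = 1.31e-07). With an estimated correlation 0 held (adjusted p from 0.114 to 0.557) and 1 passed by fry, endothelial markers (adjusted p = 0.00296). Reassigning genotypes within each age gave up to 16.

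Between 3 and 5 months, control livers differed in many genes, and this contrast also compares array series. Metallothionein genes, which bind zinc and copper, were higher at 5 months (Mt2 8.86-fold, log2 3.15 ± 0.66, adjusted p = 0.00562; Mt1 5.56-fold, 2.48 ± 0.57). The size of both rests on 5-month controls 1 and 2, with Mt2 at 2.63 and 1.52 against -2.24 to -1.06 in the other 3 and -3.85 to -2.80 at 3 months, and without control 1 the Mt2 difference was 2.47. Dbp, a clock-controlled transcription factor, was 5.93-fold higher (2.57 ± 0.41, adjusted p = 0.00126) and the mitotic kinase gene Wee1 5.02-fold (2.33 ± 0.32). Tubb2a, a beta-tubulin gene, was 7.62-fold lower (-2.93 ± 0.44, adjusted p = 0.000829) and Clpx, a mitochondrial chaperone, 4.36-fold (-2.12 ± 0.25). Ddc, dopa decarboxylase, was 3.68-fold lower (-1.88 ± 0.28) and Cyp26a1, which degrades retinoic acid, 3.36-fold (-1.75 ± 0.31). The class II gene H2-Aa (-1.88), choline kinase gene Chka (-1.68) and sperm channel gene Catsperg2 (2.30) also changed, each with all 5 of the 5-month mice beyond the 3-month mean. Ttc30a1 (2.25 ± 0.70, adjusted p = 0.0367) rose by 6.17 in the liver-in-Cy5 arrays and gave -1.66 in the liver-in-Cy3 arrays, so its direction rests on 1 orientation.

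Gene groups of protein synthesis, folding and respiration were lower at 5 months in controls. Oxidative phosphorylation fell in 20 of 24 measured members (21 adjusted over the list alone; Cox6c -1.33, Cox7a2 -1.03, Sdhd -0.84, Uqcrb -0.90). Ribosomal proteins fell in 17 of 27 (18 adjusted over the list alone; Rpl32 -1.28, Rps6 -1.07, Rplp1 -0.95, Rps15 -0.94). Endoplasmic reticulum stress genes fell in 10 of 19 (12 adjusted over the list alone, where 1 rose; Syvn1 -1.42, Ddit3 -0.89, Herpud1 -1.05, Manf -1.18). Glutathione and antioxidant enzymes fell in 23 of 39 and rose in 2 (24 and 3 adjusted over the list alone; Gsta3 -1.27 with a further probe at 0.69, Sod1 -0.63, Gstm2 -0.93, Prdx1 -0.85). Heat shock genes fell in 8 of 12 and rose in 2 (9 and 2 adjusted over the list alone; Bag3 -1.24, Hspa8 -1.05, Ahsa1 -0.78, Hsp90aa1 -1.17 with further probes at 0.54 and -1.26). Bile acid genes fell in 7 of 23 and rose in 1 (8 and 2 adjusted over the list alone; Abcb11 -0.97, Baat -0.76, Acox2 -0.71). Periportal genes (2 of 9 fell, and 6 fell and 1 rose adjusted over the list alone; Ass1 -0.76, Hal -0.68) and endothelial markers (3 of 16 fell, 3 adjusted over the list alone; Fcgr2b -0.58 with a further probe at 0.26, Clec4g -0.59, Kdr -0.47) passed too. These 8 lists held with an estimated correlation (adjusted p = 0.0472 for each). Another 5 passed only at the preset correlation, with adjusted p from 0.0982 to 0.288 with an estimated correlation: male-biased genes, cytochromes P450, amino acid genes, hepatocyte markers and Kupffer cell markers. All 13 passing lists were lower, and other splits of the controls gave up to 16.

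Limma called 5369 probes in controls, 2714 higher and 2655 lower. The all-probe median of the difference was 0.13. With each mouse centred on its own median the calls were 1639 higher and 4492 lower, and with quantile normalisation, where the median was -0.02, 1882 and 5146. Counts per direction are therefore relative to the scaling. Of the 5369, 4478 (83.4%) had the same direction in both dye orientations, 2641 of the 2655 lower calls but 1837 of the 2714 higher ones. Across all probes the age differences of separate orientations correlated at r = -0.43. In the liver-in-Cy5 arrays alone the count was 17546. It was 2389 without control animal 4 of 5 months, 3525 without its animal 1 and 3248 without control animal 2 of 3 months. Without the liver-in-Cy5 array of 5-month control animal 4 it was 3277.

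In knockouts, the same contrast gave higher Dbp (8.02-fold, log2 3.00 ± 0.41, adjusted p = 0.00693) and lower Tubb2a (3.78-fold, -1.92 ± 0.44, adjusted p = 0.0250). Clpx was 2.79-fold lower (-1.48 ± 0.25) and Cyp26a1 2.48-fold (-1.31 ± 0.31), and these 4 genes also changed in controls. The 5-month knockouts split by array series in many of the named genes, though the medians over all calls did not. Against the 3-month knockouts, the 1732 probes called changed by a median of 0.91 in series A and 1.07 in series B, in the called direction. Calling them with these mice favours that, but the 5369 probes called in controls gave 0.33 and 0.34. Tubb2a was -1.19 and -0.64 in animals 1 and 2 of series A but 1.31, 2.05 and 1.63 in animals 3 to 5 of series B, against 2.23 to 3.01 in the 3-month knockouts, and Clpx was -0.55 and -0.39 against 0.48, 1.17 and 0.80. Dbp was 0.63 and 0.01 in series A and -0.55, -2.11 and -1.02 in series B, against -4.08 to -2.97 in the 3-month knockouts. Elovl3 was -0.35 and -0.27 against 0.91 to 1.29, and Ndrg1 -0.17 and 0.23 against 1.05 to 1.34. Wee1, Ddc and Chka, named for controls, split likewise, with Wee1 at 1.38 and 0.93 against -0.74 to -0.39. The fatty acid elongase gene Elovl3 (-1.57), the clock repressor gene Nfil3 (-1.32) and Ndrg1 (-1.29) were lower as well, and all of these had 5 of 5 mice beyond the 3-month mean. Rgs13 (2.69), the vomeronasal receptor gene Vmn1r93 (2.58), the translation factor gene Eif3m (2.53, with a further probe at -0.07), Tmem179 (2.53) and Efcab1 (2.49, with a further probe at 0.46) were the other largest increases. These 5 were larger in the liver-in-Cy5 than in the liver-in-Cy3 arrays, as for Rgs13 with 5.22 against 0.20.

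Limma called 1732 probes in knockouts, 1460 higher and 272 lower, with an all-probe median of 0.14. Centring each mouse took that median to -0.03 and the split to 808 and 1373, and quantile normalisation took them to -0.07 and to 1205 and 2637. Without the single-array 5-month knockouts 2 and 3, which leaves 3 mice in the group, it was 13, and all 12 named genes kept their direction and lost their call (Dbp 2.78, adjusted p = 0.0503). Without animal 3 alone it was 388, without 3-month knockouts 1 or 2, which have both arrays, 509 and 702, and without 3-month knockout 3 it was 3022. Without the liver-in-Cy5 array of 5-month control animal 4 it was 1170. Of the calls, 271 of 272 lower and 1156 of 1460 higher ones had the same direction in both orientations, and across all probes the age differences of the orientations correlated at r = -0.17. At the preset correlation 10 lists passed, all lower, and fry passed 5 others, with 0 holding under the estimated correlation (adjusted p from 0.442 to 0.482) and up to 17 in other splits. For HGF and Met signalling, 1 of these, the median (-0.06) and the mean (0.02) differ in sign.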

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

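The tests of a strain segment, of array series and of the dye effect below were chosen after the results were seen, and the counts over other splits of the mice were planned. Genes of respiration and translation and macrophage markers had the largest medians, with all mice in, among the 12 lists that passed for the interaction of genotype and age. The oxidative phosphorylation list was 0.55 more positive at 5 than at 3 months (median log2 difference), Kupffer cell and macrophage markers 0.52 and ribosomal proteins 0.51. The interaction also passed at the preset correlation for endoplasmic reticulum stress (0.42), heat shock (0.42), xenobiotic-metabolising cytochromes P450 (0.38), glutathione and antioxidant enzymes (0.34), amino acid and urea metabolism (0.33), endothelial markers (0.26), bile acid genes (0.23), hepatocyte markers (0.23) and, in the other direction, fatty acid oxidation and PPAR-alpha targets (-0.22). Without 3-month control 3 the Kupffer cell median was 0.31. P450 genes gave 0.24, 0.22, 0.23 and 0.25 without 5-month controls 1 and 4, 3-month control 1 and 5-month knockout 1, and hepatocyte markers 0.13 without 5-month control 4. None of these 12 held with an estimated correlation, and chance is not excluded for their number, since 8 of 100 reassignments gave as many and the highest was 16.

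Single mice lay far from the other 4 of their group in 13 of 246 groups of values tested, and chance does this in about 1 in 20 groups. For Met these were 3-month knockout 5 (0.28, others -0.59 to -0.53) and 5-month knockout 3 (-1.57, others -0.75 to -0.45). Apol6 was -0.19 in 3-month knockout 3, Nfil3 2.25 in 3-month knockout 1, Nr1d1 -0.36 in 3-month control 5 and Ahsa1 1.11 in the same mouse. Abca3 was -0.48 in 5-month control 3, and Rpl32 -1.62 in 5-month control 4. In 5-month knockout 2, which has 1 array, Abca3 was -0.67, Cpeb2 1.38, Tmem179 0.37 and Efcab1 4.32. In 5-month knockout 3, which also has 1 array, Gstm2 was 1.13.

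St7 and Capza2, which lie beside Met on chromosome 6, were higher in knockouts at 5 months. An array series as the whole cause is argued against by St7, whose difference was 1.12 with series as a covariate, which compares knockouts 1 and 2 alone, against 0.92 without it. A segment of another strain carried along with the floxed Met alleles may raise neighbours at every age, and St7 was 0.58 higher at 3 months, which goes with it. Capza2 goes with it less well, at 0.26 (unadjusted p = 0.0554) at 3 months against 0.77 at 5 months, with an unadjusted interaction p of 0.013. Both genes were taken because they were called, and the list of 17 measured neighbours had medians of -0.07 at 3 and 0.02 at 5 months. A direct effect of the Met deletion on its neighbours would give the same values and was not tested, so both stay open.

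At 3 months 13 probes were called, Igfbp1 and Ctsc among them. As many were called in 3 of 100 splits, the real one included, which argues against chance for that number without excluding it. The highest other split, which called 887, is exactly the one that parts array series C from D. That points to a structure of the arrays. Array series as the whole cause is argued against, since all 13 probes kept their call with series as a covariate. For the 4 lists called at this age chance is not excluded, since 22 of 100 splits gave as many and the highest gave 9. Loss of c-Met, the difference the labels name, stays open as an untested explanation.

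The differences between 5 and 3 months are the third pattern. Only the real one of 100 splits called as many as the 5369 probes in controls (highest other 1) or the 1732 in knockouts (highest other 644). That argues against chance for both counts. Chance is not excluded for the 13 lists in controls (19 of 100, highest 16) or the 10 in knockouts (14 of 100, highest 17). A dye effect of the same size in both orientations cancels in the control means by design, as every control has both. Whether an unequal effect remains was not tested. The 83.4% of calls in controls with 1 direction in both orientations does not decide it, since a dye effect that cancels also lowers that share, and neither does the r = -0.43 between all-probe differences of the orientations. For 5-month control 4 the effect may be unequal, since its liver-in-Cy5 array correlated at r = -0.61 to -0.48 with those of 3 months. No other pair of liver-in-Cy5 arrays lay under -0.3, and the count in controls was lower without this array. No array series holds both ages, so age and series cannot be told apart.

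At 5 months only the real one of 100 splits called as many as the 53 probes between genotypes (highest other 2), which argues against chance. These splits do not follow array series, which is uneven between genotypes. With series as a covariate limma called 0 (3440 at an unadjusted p under 0.05). All 53 kept their direction, which calling them with these same mice favours. Chance is not excluded for the 15 lists (6 of 100, highest 17). For the interaction limma called 0 probes, with 2835 at an unadjusted p under 0.05. The fit of single arrays, which in effect counts arrays as replicates, called 149. With 0 called, all 100 of 100 assignments give as many by construction, which says nothing about chance, and the highest gave 2.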

How the results depend on the processing

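The settings by dye effect within each age, the turned or dropped array of 5-month control 4, dropping that mouse with 3-month knockout 5, the less noisy probes and single array series were chosen after seeing the data. The 4 genes that passed and were named by rule at 3 months, and the 17 at 5 months, kept their direction in all alternatives run on them, but each lost its call in 26 to 32 of 45 alternatives at 3 months and in 6 to 34 of 44 at 5 months. Cyp3a13 and H2-D1, named outside the rule, were not followed through the alternatives. Over named genes and lists, 6504 values kept direction and side of the threshold and 896 kept direction and lost the call. A further 104 gained one, 19 moved and 7 reversed. For lists, direction is that of the set test, so a median can change sign uncounted, as for interferon genes at 5 months (-0.04). Among the main counts and the Met fold changes 267 stayed, 114 moved and 9, all of them Met at 5 months, reversed. No probe lacks a value, so the missing-value filters removed nothing and say nothing about stability. The fit of single arrays estimated a correlation of -0.04 between the arrays of a mouse. Its counts therefore in effect treat arrays, and not mice, as replicates. Counts at 3 months (13 probes) became 5 without dye correction, 66 in the fit of single arrays, 3 with a replicate block, 22 with quantile normalisation, 0 with only both groups fitted, 27 with array series as a covariate, 2 in liver-in-Cy5 and 2 in liver-in-Cy3 arrays, 23 without the single-array mice, 26 with the dye effect within age, 1 with the odd array turned and 1 with it left out, 24 over the less noisy probes, and 0 within series C and 0 within D. By test, limma at an unadjusted 0.001 gave 176, the methods' t-test 83 and, adjusted, 0, and a plain 2-sample test 0. At 5 months (53) they became 515 in the fit of single arrays, 16 with a replicate block, 27 re-centred, 110 with quantile normalisation, 4 with only both groups, 0 with array series as a covariate, 2 in liver-in-Cy5 and 0 in liver-in-Cy3 arrays, 27 with probes averaged, where fewer are tested, 21 without the single-array mice, 8 with the odd array turned, 12 without 5-month control 4 and 3-month knockout 5, 210 over the less noisy probes and 2 within series A. By test they were 233, 186 and, adjusted, 4, and 0. The interaction (0) gave 149 in the fit of single arrays, 79 at an unadjusted 0.001 and 3 over the less noisy probes. In controls (5369) the age count was 17546 in liver-in-Cy5 arrays, 1897 with the odd array turned, 3277 without it and 2805 without 5-month control 4 and 3-month knockout 5, and by test 2187 at an unadjusted 0.001, 1535 by the methods' t-test and 2519 by the plain test. In knockouts (1732) it was 772 in the fit of single arrays, 3842 with quantile normalisation, 267 with only both groups, 10207 in liver-in-Cy5 and 5 in liver-in-Cy3 arrays, 13 without the single-array mice, 447 over the less noisy probes, 978 at an unadjusted 0.001, 625 by the methods' t-test and 257 adjusted, and 45 by the plain test. Met at 5 months (-0.05) turned to 0.05 in the fit of single arrays and with quantile normalisation, 0.13 with array series as a covariate and within series A, 0.34 in liver-in-Cy3 arrays, 0.20 without the single-array mice and 0.03 without the odd array. Ttc30a1 in controls turned to -1.66 in liver-in-Cy3 arrays. There, lists in knockouts between ages were male-biased genes -0.09, fatty acid synthesis -0.02, amino acid genes 0.03, endoplasmic reticulum stress -0.15, oxidative phosphorylation -0.04 and hepatocyte markers 0, with the test's direction turned. Of the lists at 3 months (4), 9 passed in the fit of single arrays, 7 with only both groups, 7 by the methods' test, 2 in liver-in-Cy5 arrays, 9 over the less noisy probes, 2 within series C and 7 within D, 1 with the estimated correlation and 1 by fry, and at 5 months (15) 1 and 6. Fewer mice or probes enter the fits of single orientations, single series and averaged probes, and otherwise the cause was not tested.

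Leaving out each mouse in turn gave 0 to 26 probes at 3 months, 10 to 105 at 5 months, 0 to 1 for the interaction, 2389 to 6535 in controls and 388 to 3022 in knockouts between ages, -0.17 to 0.14 for Met at 5 months and 3 to 8 lists at 3 months. At 3 months the probe count was 1 without 5-month control 2, 4 or 5 or knockout 1, 4 or 5, 3 without control 3 or knockout 2 of that age, 26 without its knockout 3, 0 without 3-month control 2 or knockout 1, 2 without control 4, and 4 without controls 3 or 5 or knockouts 3 or 4. At 5 months it was 20, 34, 105, 10 and 17 without 5-month controls 1 to 5, 28, 32, 11 and 11 without knockouts 1, 3, 4 and 5, 31, 31 and 32 without 3-month controls 2, 3 and 4, and 31, 29 and 28 without knockouts 2, 3 and 4. The interaction gave 1 without 5-month knockout 2 or 3-month control 5. Between ages, controls gave 3525 and 2389 without 5-month controls 1 and 4 and 3248 without 3-month control 2. Knockouts gave 1067, 388, 1024 and 935 without 5-month knockouts 1, 3, 4 and 5, and 509, 702, 3022 and 1126 without 3-month knockouts 1 to 4. Lists at 3 months were 8 without 3-month control 1, those of the interaction 7, 7, 7, 6 and 6 without 5-month control 1, knockout 2, 3-month controls 1 and 4 and knockout 3, and those of knockouts between ages 16 without 5-month knockout 1 or 2. Met at 5 months turned without knockout 3 (0.14) or control 5 (0.04) of that age. Of lists that passed, leaving out 1 mouse ended the call at 3 months for HGF and Met signalling (0.12 without control 3, 0.09 without control 5, 0.06 without knockout 5) and oxidative phosphorylation (-0.16 without knockout 3), and moved pericentral genes to 0.15 without control 1. At 5 months it ended the call of bile acid genes (0.14, 0.12, 0.16, 0.15 and 0.14 without controls 1 and 4 and knockouts 1, 2 and 5), interferon genes (0.14, 0.13, 0.07 and 0.14 without controls 2 and 3 and knockouts 4 and 5, 0.16 without 3-month knockout 1) and pericentral genes (0.14 without control 4, 0.22 without knockout 5). It moved others at 5 months without ending the call: glutathione enzymes to 0.15 and male-biased genes to 0.22 without control 4, cytochromes P450 to 0.29 without control 1, Kupffer cell markers to 0.30 without control 5, and fatty acid oxidation to -0.08, -0.24, -0.28 and -0.24 without controls 1, 3 and 4 and knockout 1. In controls between ages, endothelial markers lost their call without 3-month control 2 (-0.23) or 4 (-0.20), and bile acid genes moved to -0.22 without 5-month control 4. Several interaction lists lost their call without many of the 20 mice, as heat shock did without 13 and bile acid genes without 11. In knockouts between ages, HGF and Met signalling lost its call without any 1 of 10 mice and amino acid genes without any 1 of 4. Fatty acid and triglyceride synthesis lost it without any 1 of 3, with a median from -0.16 to 0.09. Male-biased and endoplasmic reticulum stress genes lost it without 1 mouse each, and the latter's median ran from -0.23 to -0.05. The other lists passing there kept their call.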

Other observations

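Core clock and clock-output genes differed both ways between ages. In controls Dbp (2.57), Per3 (1.07), Per2 (1.01), Nr1d2 (0.76), Tef (0.72) and Cry2 (0.71) were higher at 5 months, and Nfil3 (-1.05), Per1 (-1.04), Clock (-0.83) and Nr1d1 (-0.62) lower, 6 and 4 of 16 measured and the same numbers adjusted over the list alone. In knockouts Dbp (3.00), Nr1d2 (1.34), Tef (1.08), Per3 (1.06) and Nr1d1 (0.77) were higher and Nfil3 (-1.32) and Per1 (-0.69) lower, with 6 and 3 adjusted over the list alone. As a set the clock list did not pass in either genotype (adjusted p = 0.993 and 0.387). These members were chosen after their values were seen. Each gene is given by 1 probe, and the probes of Nr1d1 disagreed in the interaction. Age and array series cannot be told apart here. Dbp in 5-month knockouts was 0.63 and 0.01 in series A and -0.55, -2.11 and -1.02 in series B. The hour of collection is not given in the sources used here.

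Tumour-associated genes varied among the 5-month knockouts, and these values were picked after they had been seen. H19, a fetal liver RNA, was -0.10, -0.02, 3.31, 3.15 and 2.23 in knockouts 1 to 5, against 0.09 to 1.33 in controls. Afp, alpha-fetoprotein, was 0.15, 0.14, 1.46, 2.51 and 0.50 against 0.50 to 0.95. Akr1c18, a steroid reductase gene, was 1.31, 0.35, 2.73, 3.15 and 1.98 against 0.33 to 0.90, and Scd2, a fatty acid desaturase gene, 0.38, 0.40, 2.27, 1.85 and 1.37 against 0.10 to 0.40. Gpc3, another tumour marker, showed no such rise (0.24, 0.65 and 0.49 in knockouts 3 to 5, against -0.10 to 1.20 in controls), and the tumour marker list did not pass. None of these genes passed between genotypes over all probes. Knockouts 3, 4 and 5 are also the mice of array series B, which holds no control, so mouse and series cannot be told apart, and H19 and Afp were part of the basis for the direction of the ratio.

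Genes called at 5 months were spread unevenly over chromosomes without passing a test chosen after the calls were seen. Chromosome 6 held 7 of 35 called genes with 2.21 expected (adjusted p = 0.0552) and chromosome 17 held 6 with 1.61 expected (adjusted p = 0.0552). On chromosome 6 these were St7, Capza2, Rpl32, Nat8f5, Mug1, Mug2 and Mgll. On chromosome 17 they were H2-Bl, Glo1, Abca3, Slc22a7, Dynlt1b and Elob. At 3 months H2-Bl differed by 1.05, Dynlt1b by 0.73, Glo1 by 0.61 and Slc22a7 by -0.87, but Abca3 by 0.10 and Elob by 0.03. A strain segment was weighed for St7 and Capza2 alone, so a strain difference at the others was not tested.

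Replicate numbers did not pair mice across groups, as the same number was the best match in 1 of 5 cases for each pair of groups tested.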
